A study of Danio rerio with 20 samples.

How the data were processed

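The data were 20 Agilent 2-colour zebrafish arrays. On 18 of the samples' arrays the Cy5 dye marked RNA of embryos exposed to a particle extract and Cy3 marked RNA pooled from DMSO control embryos. There were 6 extracts with 3 pools of 20 embryos each, labelled from 200 ng of RNA. The remaining arrays were a technical repeat of rural November replicate 1 and a self-to-self array with the urban PM10 February extract in both channels. No array had the dyes swapped. Per the labels, the fine particle fraction is PM1, whereas the study's own text gives it a smaller diameter, and the text places all sampling in the cold season although 2 urban extracts are from May. The label names are used here.

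Per the file headers, the authors scanned the arrays and read them with Agilent Feature Extraction 10.5.1.1. The deposited scanner files give the spot and local background brightness per channel as raw intensity, and a log10 ratio of Cy5 over Cy3 after background subtraction and dye normalisation. The deposited table of the whole series holds log2 ratios of Cy5 over Cy3, normalised within each array by the authors, with no header that names the method. Other columns of the deposited files are flags of 0 or 1. Correlation of these log2 ratios with those computed here was 0.997 or higher across probes on every array. The probe design was annotated on the older genome build Zv8, and no coordinates are given.

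Log2 ratios were computed from the scanner files with limma 3.58.1 in R 4.3.3, with files read by the data.table package (1.17.8). The plan named mean spot signals and the gene name column, but the files hold neither, so median spot signals were used. Background was corrected by normexp with an offset of 50 and each array was normalised by loess. Spots with a non-uniformity flag in either channel were set to missing, which was 0.0271% of spots, and 0 spot readings were saturated. Of 43603 probes, 25069 (57.5%) matched a gene symbol through the transcript accession on the array and the gene table of the GRCz12tu assembly, which was used for names alone. A probe was kept if it was well above background in all 3 samples of at least 1 extract in Cy5, or on the same arrays in Cy3. The brightest probe stood for each gene, a probe without a symbol counted as its own gene, and a gene needed values in 2 samples of every extract. This left 24655 genes, 11801 of them with a symbol and 12854 without. Probes of close paralogs, such as crystallins, trypsins and globins, can bind each other's transcripts, and this was not tested. The number of arrays, not the number of probes, limits the precision.

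The technical repeat was averaged with its own sample. 1 limma model (lmFit and eBayes) with 1 mean per extract was fitted to the 18 samples, with 12 residual and 3.25 prior degrees of freedom, and gave all 13 comparisons. P-values were two-sided and adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05, and ± after a difference is the standard error of the model. A comparison with control tests the mean log2 ratio against 0. It leaves out the spread of the control itself and any gene-specific dye effect, because every exposed sample was in Cy5. Each site, month and particle size is 1 extract, so all p-values measure the spread between embryo pools and not between filters or days. The plan assumed that the control cancels in a difference between extracts, but the Cy3 signal differed between the arrays of the sites. The Cy5 channel alone was therefore compared too, after normalisation between arrays (Aquantile), an alternative chosen after seeing the data, with and without the slide. Between the sites, correlations of log2 ratios across genes had a median of −0.22 and ran from −0.65 to 0.74 over 72 pairs of arrays. The labels state the dye of every sample and the largest AhR genes had 1 direction on all 18 arrays, so no array was turned.

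A total of 26 gene lists was fixed before the data were examined, as were the comparisons, the naming rule and all alternative settings but those for Cy5 alone and for the urban pairs described below. They cover the aryl hydrocarbon receptor (AhR) battery, other responses to chemicals and stress, organs and cell types, metabolism, hormones and the clock, and 531 of their 690 members were measured. They were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, in 5 main comparisons, adjusted over lists and comparisons together. Camera compares a list with the other genes, and fry tests whether its members moved on balance 1 way. The 154 missing values were filled by the mean of their extract for these tests alone. No list called at the preset correlation held with the estimated one, except the photoreceptor list between PM10 and PM1. For each main comparison the 10 largest rises and 10 largest falls past the threshold were named, if their sign was the same in every sample. Up to 4 members per list past the threshold and every AhR member were added, and other comparisons gave 5 and 5. Against control, a gene also had to keep its sign and 0.5 of its log2 ratio after the self-to-self ratio was subtracted. Genes chosen after their values were seen are marked. A gene that the rule named and a list are not reported here.

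The model was tested on simulated data of the same size and spread, with independent noise for every gene and sample. With a log2 change of 1, it recovered 98.5% of the changed genes for urban against control, 100% for rural against control, 88.1% between the sites, 95.5% between PM10 and PM1, 88.1% between the urban months and 74.6% between the rural months. With a change of 0.5 it recovered 92.5%, 83.6%, 49.3%, 53.7%, 62.7% and 19.4% in the same order. False calls numbered 4 to 18 of 24655 genes. The simulation held no correlation between genes, no pairs of samples and no shift of the control. It therefore does not measure false calls or recovery where these are present. Urban PM10 and PM1 samples of the same month and number were taken as pairs in further fits. Their deviations from the extract means correlated across genes at 0.288 to 0.891 in 6 of 6 pairs, all above 0.1, and the 2 samples of each pair shared a slide. No label states what else they share, so the source of this correlation is unknown. Deviations from a mean are tied within each extract, so the 6 values are not independent. PM10 May replicate 3 correlated more with PM1 May replicate 2 (0.543) than with its own number (0.503). Over all extracts, 5 of the 18 samples correlated best with a sample of their own number. The pairing is therefore not certain. The numbers did not pair other samples, since 21 of the other 39 pairs of the same number were above 0.1, with a range from −0.847 to 0.727. The model has no block, as planned, and treats the 12 urban samples as independent. Fits that take up the pairs, chosen after seeing the data, put them in as a block for PM10 against PM1 and size by month (8 residual degrees of freedom), and as a random effect (duplicateCorrelation) for urban against control and the urban months. List p-values of the block fit were adjusted together with those of the other 4 main comparisons.

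The alternatives were no background subtraction, the deposited log2 ratios, median centring in place of loess, no filter or a strict filter on dim probes, the mean of a gene's probes, a block for the replicate number, slide or scan day, a dye term from the self-to-self array, eBayes with trend and robust variances, the technical repeat left out, and each sample left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.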

Results

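Zebrafish embryos were exposed from 24 to 120 hours after fertilisation to the organic extract of airborne particles, and RNA of the whole animals was measured at 5 days. Each extract was diluted 500-fold in embryo water with 0.2% DMSO. An urban site gave 4 extracts, of PM10 and of the finer PM1, from May and from February. A rural site gave 2 extracts, of PM1 from November and December. Each extract was given to 3 pools of 20 embryos, which makes 12 urban and 6 rural samples, and every sample shared its array with a pool of DMSO control embryos. The share of probes well above background was 72.2% to 86.4% in the Cy5 channel of the exposed embryos. In the Cy3 channel of the control it was 47.8% on the array of urban PM10 May replicate 1 and up to 87.4% on the others. The median Cy5 signal of an array was 135 to 265 over a median local background of 54 to 57. The technical repeat of rural November replicate 1 correlated with its first array at r = 0.811 across probes, which are not independent replicates, with a median absolute difference of 0.13 log2 units. Pools exposed to the same extract varied widely. Their log2 ratios correlated across genes at a median of 0.47 over 18 pairs, with a lowest value of −0.32 and a highest of 0.89.

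The first question was which genes the urban extracts changed. Embryos exposed to them raised the genes of the aryl hydrocarbon receptor (AhR), which binds polycyclic aromatic hydrocarbons and dioxins and switches on enzymes that break them down. These included the monooxygenases cyp1a, cyp1c1 and cyp1b1 and the receptor's own repressor, ahrra. The oxygen-sensing hydroxylase egln3 and the endosomal gene plekhf1 rose too, as did ela2 and other digestive enzymes of the exocrine pancreas. Arrestin arr3b, which silences cone opsins after a light response, fell, as did fosab and klf4, transcription factor genes that respond quickly to stimulation.

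The rise of cyp1a was 2.85 ± 0.20 log2 units, or 7.19-fold, and was above control in 12 of 12 samples (adjusted p = 2.15e-07). cyp1c1 rose 2.74-fold (log2 1.45 ± 0.10), ahrra 2.29-fold (1.19 ± 0.05) and cyp1b1 1.66-fold (0.73 ± 0.09), each in 12 of 12 samples. Of the 15 AhR members measured, 9 rose and 6 did not pass, and the counts were the same adjusted over the list alone. With the urban pairs as a random effect ahr2, among the 9, did not pass. Among the 6 was nqo1, a quinone reductase (0.40 ± 0.17, adjusted p = 0.0874, above control in 8 of 12 samples). The list had a median of 0.40 and passed camera (adjusted p = 2.49e-05, and adjusted p = 0.28 with an estimated correlation). The rise of tiparp (0.45 ± 0.05) was close to its self-to-self ratio, which was 0.41.

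**Figure D1:**
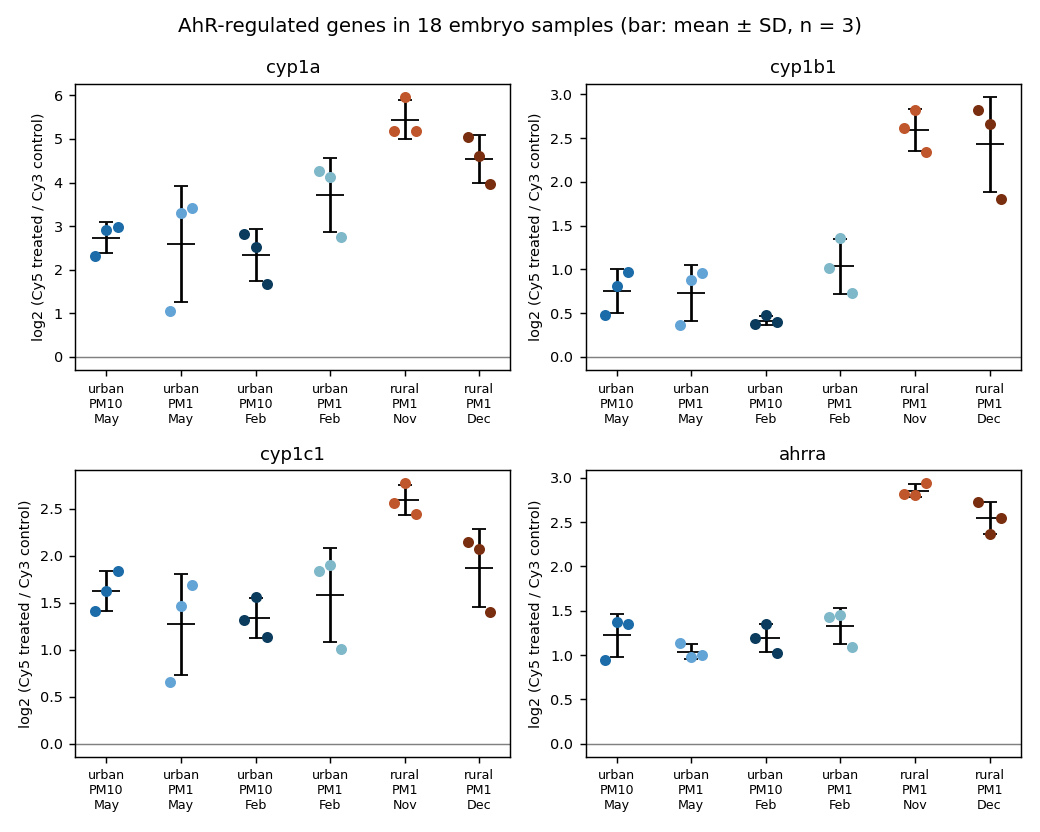
Log2 ratio to control of cyp1a, cyp1b1, cyp1c1 and ahrra (vertical axis) in each of the 18 samples by extract, with points for samples and bars for the mean ± SD of 3. The means of cyp1a run from 2.34 with urban PM10 February to 5.44 with rural November.

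Pancreatic transcripts were the group with the largest median rise in urban embryos. ela2 rose 4.23-fold (2.08 ± 0.30, in 11 of 12 samples), the elastase gene ela2l rose by 1.51 ± 0.23, the chymotrypsinogen ctrb.1 by 1.26 ± 0.16 and the lipase cel.1 by 1.14 ± 0.13. Of 15 pancreatic members measured, 14 rose over all genes and 15 adjusted over the list alone (median 1.51, camera adjusted p = 6.5e-08, and 0.505 with an estimated correlation). Liver and blood genes rose too. Ceruloplasmin cp rose by 1.11 ± 0.14, fetuin ahsg1 by 1.25 ± 0.24 and transthyretin ttr 2.29-fold, and 6 of 20 liver and plasma members rose (median 0.57, adjusted p = 0.0019, and 0.757 with an estimated correlation), 6 adjusted over the list alone. The embryonic globin hbae3 rose by 1.01 ± 0.17 and alas2, the first enzyme of haem synthesis in red cells, by 0.69 ± 0.06. Of 14 erythroid members 9 rose (median 0.31, adjusted p = 0.000681, and 0.541 with an estimated correlation), 9 adjusted over the list alone. Lens crystallin genes rose in 19 cases and fell in 1 of 35, and in 20 and 1 adjusted over the list alone (median 0.29, adjusted p = 3.31e-05, and 0.613 with an estimated correlation). The intestine list had 8 rises of 19, and 12 with 1 fall adjusted over the list alone (adjusted p = 0.00615, and 0.745 with an estimated correlation). Its median was below 0 in PM10 May replicate 1 (−0.18), PM1 May replicate 1 (−0.59), PM10 February replicate 3 (−0.39) and PM1 February replicate 3 (−0.88). The lens median was below 0 in PM1 May replicate 1 (−0.13) and PM1 February replicate 3 (−0.18).

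Genes of defence against oxidants and of drug metabolism rose in part. Among 21 members of the Nrf2 and glutathione list 12 rose, such as glutathione reductase gsr (0.58 ± 0.13) and the sensor keap1a (0.45 ± 0.10), with 12 adjusted over the list alone (adjusted p = 0.00231, and 0.718 with an estimated correlation). Of 23 conjugation and transport genes 7 rose, led by the sulfotransferase sult6b1 (1.07 ± 0.21), and 6 adjusted over the list alone (adjusted p = 0.00324, and 0.752 with an estimated correlation). The medians of the Nrf2, conjugation and liver lists were all below 0 in PM1 May replicate 1 (−0.37, −0.37 and −0.81), PM10 February replicate 3 (−0.18, −0.34 and −0.31) and PM1 February replicate 3 (−0.33, −0.57 and −0.89), and in PM10 May replicate 1 they were 0.02, −0.17 and −0.30. For sterol synthesis 9 of 24 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0417, and 0.792 with an estimated correlation). Its feedback regulator insig1 rose by 0.81 ± 0.07.

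In the other direction arr3b fell by 1.37 ± 0.05 in 12 of 12 samples (adjusted p = 8.83e-11), fosab by 1.03 ± 0.11, klf4 by 1.01 ± 0.10, the apoptosis inhibitor faima by 0.97 ± 0.08 and the fatty acid carrier fabp4b by 0.95 ± 0.10. The photoreceptor list had 20 falls and 6 rises among 41 members, and 22 and 7 adjusted over the list alone (median −0.14, adjusted p = 1.72e-05, and 0.487 with an estimated correlation), and this direction turned to 0.26 under median centring. The neural list had 10 falls and 2 rises of 25, and 13 and 2 adjusted over the list alone (−0.16, adjusted p = 0.00615, and 0.613 with an estimated correlation), and turned to 0.20. The chaperone list had 11 falls, such as the endoplasmic reticulum chaperone hspa5 (−0.69 ± 0.06), and 4 rises of 23, and 11 and 5 adjusted over the list alone (−0.11, adjusted p = 0.0243, and 0.487 with an estimated correlation), and turned to 0.23. Median centring moved the median of all genes by 0.11, to 0.12. Relative to that level the lists were at 0.14, 0.08 and 0.11.

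The other 14 lists did not pass camera in the urban embryos, and the counts of 13 of them follow. Cell cycle genes and leukocyte markers each had 5 rises. Rises and falls over all genes numbered 2 and 5 for inflammation, 4 and 5 for the circadian clock, 8 and 2 for epidermis, 6 and 2 for fatty acid oxidation, and 6 and 4 for glucocorticoid and gluconeogenesis genes. They numbered 5 and 1 for the heart, 3 and 3 for lipogenesis, 1 and 2 for metallothionein and hypoxia, 8 and 2 for skeletal muscle, 3 and 2 for thyroid and oestrogen genes, and 2 and 2 for cartilage and bone. The clock genes went both ways, with nr1d2a at −0.81 ± 0.07 and bhlhe40 at 0.92 ± 0.07. Inflammation genes included the metalloprotease mmp9 at −0.63 ± 0.11. Among these 14 lists fry called the leukocyte list (adjusted p = 0.0148) and the thyroid and oestrogen list (0.049). Of the lists that camera called, fry did not call liver, intestine and conjugation (0.0817 for each).

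In all, 8998 of 24655 genes passed against control in the urban embryos, 5030 above and 3968 below, and 96 of them changed by 2-fold or more. Median centring gave 14402 genes, 10375 above and 4027 below, and a slide block gave 5631. The test ignores dye effects. With a dye term taken from the single self-to-self array only 1 gene passed and 977 had an unadjusted p under 0.05, so the cyp1a rise lost its call there while its value stayed at 2.71. The 1 gene is a probe without a symbol that fell by 1.69. The Cy3 control level of fosab was 10.8 log2 units on these arrays and 9.05 on the rural ones, so its fall here is relative to a control with more of it. Mean Cy3 signals on urban and rural arrays were 9.01 and 9.38 for the erythroid list and 11.1 and 11.5 for the Nrf2 list. They were 8.78 and 9.34 for the conjugation list and 11.1 and 12.2 for the pancreas list. Urban Cy5 signals were 9.37, 11.4, 9.17 and 12.5 in this order, so these rises are relative to a control with less of them. The Cy3 signals of the lens (12.7 and 12.8) and AhR (8.12 and 8.22) lists lay closer together.

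The 4 urban extracts were next set against control singly. cyp1a rose with each of them, as did at least 1 of the pancreatic or oxygen-sensing genes, and arr3b fell with each. The changes with PM10 from May included a rise of bhlhe40, a repressor of the clock, and a fall of aanat2, which makes melatonin in the pineal gland and eye. PM1 from May and PM10 from February raised the digestive enzymes amy2a or amy2al2 and ela2. PM1 from February gave the largest cyp1a value of the 4.

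With PM10 May, bhlhe40 rose by 1.62 ± 0.15, the activin subunit inhbb by 1.40 ± 0.09 and egln3 by 2.26 ± 0.37, while aanat2 fell by 1.43 ± 0.25 and the guanylate cyclase activator guca1aa by 1.26 ± 0.13. With PM1 May, amylase amy2a rose by 2.47 ± 0.69 and ela2 by 2.42 ± 0.61, and arr3b fell by 1.62 ± 0.09 and fabp4b by 1.34 ± 0.20. With PM10 February, ela2 rose by 2.61 ± 0.61 and amylase amy2al2 by 2.20 ± 0.58, and fosab fell by 1.24 ± 0.22. With PM1 February, cyp1a rose 13.1-fold (3.71 ± 0.39) and plekhf1 by 1.64 ± 0.27, and the cone kinase grk7a fell by 1.26 ± 0.10 and fosab by 1.35 ± 0.22. The rise of cyp1a was 6.66-fold with PM10 May, 6.05-fold with PM1 May and 5.05-fold with PM10 February. Each of these held in 3 of 3 samples.

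The counts rest on 3 pools each and moved with single pools. PM10 May called 1009 genes (678 above, 331 below), and 417, 404 and 241 without its replicates 1, 2 and 3. PM1 May called 1676 (961 above, 715 below), and 4991, 232 and 394 without its replicates. PM10 February called 1140 (620 above, 520 below), and 253, 126 and 295 without its replicates. PM1 February called 897 (426 above, 471 below), and 218, 145 and 587 without its replicates, and 1404 without PM1 May replicate 1, which also feeds the shared spread. Median centring gave 5342 above and 1590 below for PM10 May, 5231 and 747 for PM1 May, 2731 and 286 for PM10 February, and 490 and 81 for PM1 February. A slide block gave 257, 803, 531 and 324 genes in the same order. With the dye term 1, 3, 1 and 2 genes passed, arr3b among them for both PM1 extracts and arr3a for PM1 May, seen after the values, with 987, 1270, 743 and 801 at an unadjusted p under 0.05.

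The rural extracts addressed the same question for countryside air. They too raised genes of the AhR, among them cyp1a, ahrra, cyp1b1 and cyp1c1. fosab, npas4a, jdp2b, egr4 and klf4, which encode transcription factors that cells switch on within minutes of a stimulus, rose beside them, as did ptgs2b, which makes prostaglandins. No list of such early genes was tested. Genes of the lens, the gut and the liver fell, among them the crystallin crygm2d13, the apolipoprotein apoa2 and the intestinal glucose transporter slc5a1, as did the enamel-type matrix gene scpp5. Cell division genes such as cdc20 and plk1 fell as well.

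cyp1a rose 31.9-fold in the rural samples (4.99 ± 0.28, 6 of 6 samples, limma adjusted p = 3.95e-08). ahrra rose 6.51-fold (2.70 ± 0.07), cyp1b1 5.7-fold (2.51 ± 0.12), cyp1c1 4.7-fold (2.23 ± 0.14), cyp1c2 2.16-fold (1.11 ± 0.10) and the receptor gene ahr2 1.63-fold (0.71 ± 0.11). Of 15 AhR members 9 rose and 2 fell, nqo1 by 0.83 ± 0.25 and cyp1d1 by 0.41 ± 0.13, with the same counts adjusted over the list alone (median 0.29, camera adjusted p = 1.72e-05, and 0.28 with an estimated correlation). fosab rose 6.01-fold (2.59 ± 0.15), npas4a by 2.32 ± 0.11, jdp2b by 2.31 ± 0.13, egr4 by 1.55 ± 0.09, klf4 by 1.47 ± 0.15 and ptgs2b by 1.34 ± 0.07. The rises of fosab, npas4a and klf4 are relative to a control with less of them than on the urban arrays. For fosab the Cy3 signals were 8.94 to 9.21 log2 units on rural and 10.64 to 10.95 on urban arrays. Its Cy5 signals were 10.86 to 12.59 in rural and 8.79 to 10.42 in urban embryos. Of 14 inflammation members 8 rose, such as the cytokine brake socs3a (1.33 ± 0.16) and the NF-kappaB inhibitor nfkbiaa (0.60 ± 0.08), 8 adjusted over the list alone (median 0.43, adjusted p = 0.000955, and 0.487 with an estimated correlation). The control level of this list was lower on the rural arrays, with a mean Cy3 signal of 9.22 against 9.76 on the urban ones, while the mean Cy5 signal was 9.63 in rural and 9.64 in urban embryos.

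Organ and metabolic genes fell in the rural embryos, relative to a control pool whose levels over several of these lists were higher than on the urban arrays. crygm2d13 fell by 2.48 ± 0.51, and of 35 lens members 23 fell, 24 adjusted over the list alone (median −0.46, adjusted p = 1.02e-08, and 0.505 with an estimated correlation). apoa2 fell by 2.41 ± 0.57, and 12 of 20 liver members fell, 14 adjusted over the list alone (−0.95, adjusted p = 8.13e-05, and 0.677 with an estimated correlation). slc5a1 fell by 2.27 ± 0.54, with 12 falls and 1 rise of 19 intestine members, and 14 and 2 adjusted over the list alone (−0.96, adjusted p = 0.000498, and 0.636 with an estimated correlation). ela2 fell by 2.00 ± 0.43, and 6 of 15 pancreatic members fell, 7 adjusted over the list alone (−0.73, adjusted p = 0.00107, and 0.692 with an estimated correlation). The glutathione transferases gsta.1 (−2.05 ± 0.42) and gstp1.1 (−1.69 ± 0.21) fell too. Conjugation genes had 12 falls and 1 rise of 23, and 16 and 1 adjusted over the list alone (−0.56, adjusted p = 0.000126, and 0.636 with an estimated correlation).

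Most members of the cell cycle list were below control, against a control pool whose level over this list was 10.2 log2 units, with 9.81 on the urban arrays, while the Cy5 levels were 9.85 in rural and 9.87 in urban embryos. cdc20 was at −0.68 ± 0.10, plk1 at −0.59 ± 0.09, the cyclin ccnb1 at −0.59 ± 0.09 and the replication licensing gene mcm3 at −0.47 ± 0.07, and 17 of 20 members fell and 1 rose, the same adjusted over the list alone (median −0.47, adjusted p = 1.76e-07, and 0.487 with an estimated correlation). Fatty acid oxidation had 15 falls and 2 rises of 26 (adjusted p = 0.000956, and 0.505 with an estimated correlation), and 17 and 3 adjusted over the list alone. Sterol synthesis had 13 falls and 2 rises of 24 (0.000276, and 0.542 with an estimated correlation), the same adjusted over the list alone. The heart list had 9 falls of 15 (0.00175, and 0.541 with an estimated correlation), 10 adjusted over the list alone, among them the atrial peptide nppa (−0.34 ± 0.08). The Nrf2 list had 10 falls and 2 rises of 21 (0.00179, and 0.702 with an estimated correlation), and 14 and 2 adjusted over the list alone. Epidermis (7 falls, 2 rises of 25), cartilage and bone (9 and 1 of 19), chaperones (10 and 6 of 23) and photoreceptors (11 and 1 of 41) passed camera at adjusted p of 0.00645, 0.0351, 0.0387 and 0.044, and had 0.835, 0.487, 0.505 and 0.745 with an estimated correlation. With a slide block epidermis passed and the other 3 did not, with medians of −0.16, −0.21 and −0.02 against −0.20, −0.24 and −0.05. The other 10 lists did not pass camera. Among them fry called the clock list (9 rises, 1 fall, adjusted p = 0.00801) and the leukocyte list (5 falls, 1 rise, 0.0461). Of the lists that camera called, fry did not call conjugation (0.0681), intestine (0.0736), photoreceptors (0.0919), liver (0.0948), pancreas (0.0948), Nrf2 (0.132) and epidermis (0.197).

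**Figure D2:**
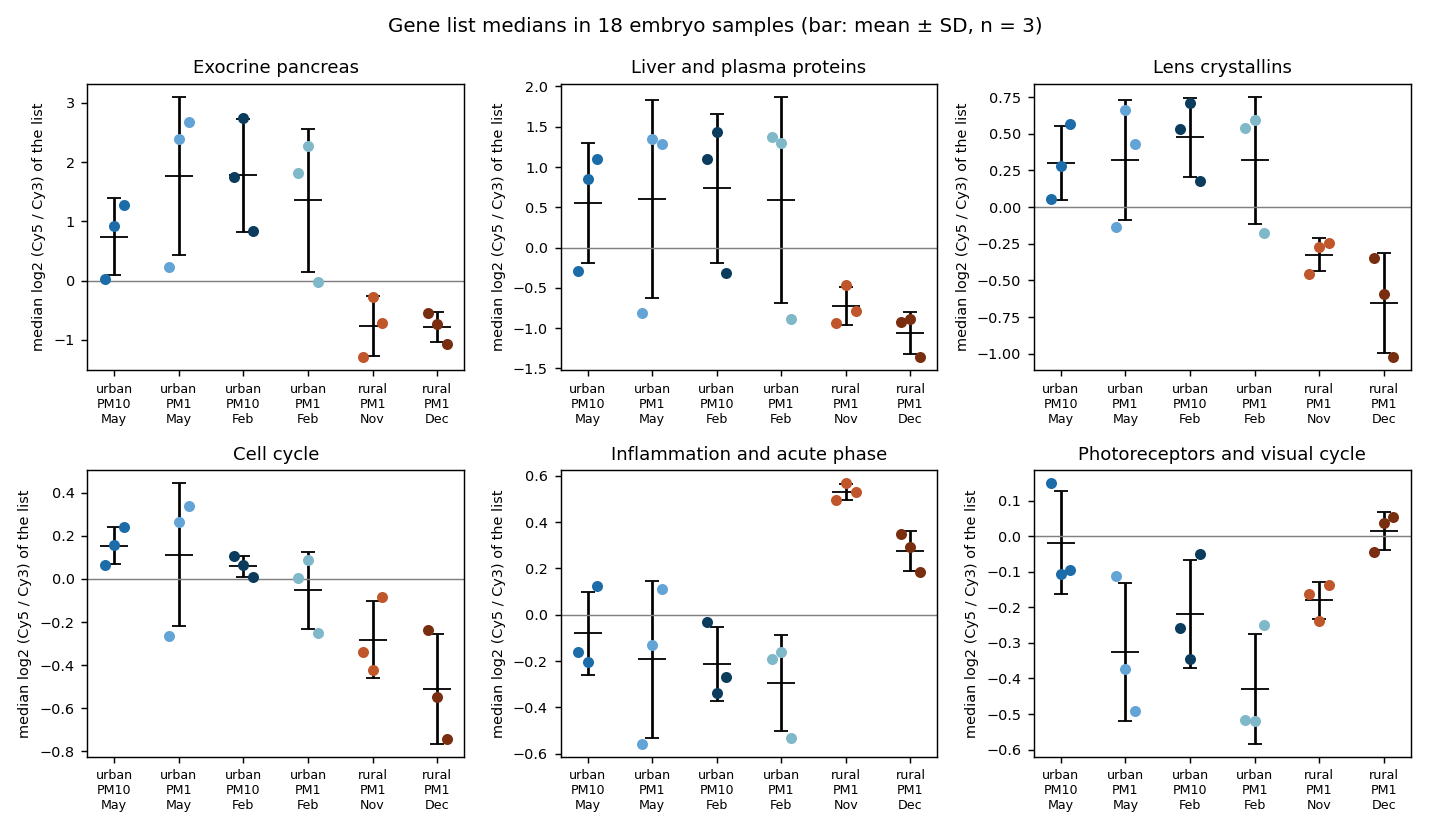
Median log2 ratio to control of 6 gene lists (vertical axis) in each of the 18 samples by extract, 1 point per sample. Pancreas medians run from −0.01 to 2.75 in urban samples and from −1.29 to −0.28 in rural ones, the urban photoreceptor direction turned from −0.14 to 0.26 under median centring, and the site difference of the cell cycle list was −0.06 in the Cy5 channel alone.

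A total of 7892 genes passed for the rural extracts, 3865 above and 4027 below, 304 of them by 2-fold or more. The count was 4461 without November replicate 1, 5015 without November replicate 2 and 4435 without December replicate 3, and median centring gave 2931 above and 1857 below. With the dye term 14 genes passed, all above control, and 1194 had an unadjusted p under 0.05. They were cyp1a, ahrra, cyp1b1, cyp1c1, fosab, npas4a, jdp2b, egr4, ptgs2b, ier2a and 4 probes without a symbol, and ier2a is named here after its value was seen. The rural control pool held more of ela2 (15.0 log2 units in Cy3, against 12.6 on the urban arrays) and of apoa2 (15.0 against 13.4), to which their falls are relative.

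By extract, cyp1a rose 43.5-fold with November (5.44 ± 0.39) and 23.3-fold with December (4.54 ± 0.39), each in 3 of 3 samples. November raised fosab by 3.25 ± 0.22, ahrra by 2.85 ± 0.10 and jdp2b by 2.75 ± 0.19, while the vitamin B12 carrier tcnba fell by 1.80 ± 0.44 and gstp1.1 fell by 1.54 ± 0.29. December raised npas4a by 2.33 ± 0.15 and ahrra by 2.55 ± 0.10, while crygm2d13 fell by 3.02 ± 0.72 and apoa2 fell by 2.76 ± 0.81. November called 535 genes (407 above, 128 below), and 157 and 96 without its replicates 1 and 2 and 982 without PM1 May replicate 1. It called 356 with a slide block, 284 (261 above, 23 below) under median centring and 15 with the dye term. December called 7379 (3636 above, 3743 below), and 4477, 2416 and 1393 without its replicates, 4090 (2880 above, 1210 below) under median centring and 5 with the dye term. Those 5 were ahrra, cyp1b1, npas4a and 2 probes without a symbol, and 515 and 2412 genes had an unadjusted p under 0.05 with the dye term in November and December.

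The next comparison asked how urban and rural PM1 differ. The early response genes fosab, jdp2b and npas4a were lower with the urban extracts. The AhR genes cyp1a, ahrra and cyp1b1 were lower too, although both sites raised them above control. Relative to control, digestive enzymes were higher with the urban extracts, such as ela2, the carboxypeptidase cpa5 and the amylase amy2a, together with crystallins and the tooth matrix genes scpp5 and odam. The control pools were not alike on the arrays of the sites, so differences were also read from the exposed embryos' own channel.

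fosab was lower with urban PM1 (log2 difference −3.69 ± 0.22, adjusted p = 1.13e-07, 12 of 12 samples beyond the other site's mean). jdp2b differed by −3.33 ± 0.19, npas4a by −3.08 ± 0.15, klf4 by −2.47 ± 0.21, egr4 by −2.27 ± 0.13 and the growth brake btg2 by −2.10 ± 0.16. cyp1a was at 0.28 times its rural level (−1.84 ± 0.39, adjusted p = 0.00765, 12 of 12), ahrra differed by −1.52 ± 0.10 and cyp1b1 by −1.63 ± 0.17. Of 15 AhR members 8 were lower and 4 higher, nqo1 among the higher (1.31 ± 0.35), with the same counts adjusted over the list alone (median −0.31, camera adjusted p = 0.0386, and 0.509 with an estimated correlation). The list did not pass with a slide block (median −0.31) and passed in Cy5 alone (median −0.17).

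In the opposite direction the ratio of ela2 to control was 17.8-fold higher with urban PM1 (4.15 ± 0.61, adjusted p = 0.000855, 12 of 12). All values of this paragraph compare ratios to control pools that differed between the sites. In the Cy5 channel alone the 10 largest rises kept a median share of 0.477 of the difference. There 10 of 10 kept their sign and 0 of 10 passed in limma. cpa5 differed by 3.68 ± 0.56, scpp5 by 3.54 ± 0.57, the apolipoprotein apoda.2 by 3.41 ± 0.69, crygm2d13 by 3.39 ± 0.72, amy2a by 3.38 ± 0.69 and the glutathione transferase gsto2 by 3.20 ± 0.51. Of 15 pancreatic members 14 were higher, and 14 adjusted over the list alone (median 2.36, adjusted p = 1.17e-09, and 0.487 with an estimated correlation). Lens genes were higher in 27 of 35 cases, 28 adjusted over the list alone (adjusted p = 1.53e-12, and 0.487 with an estimated correlation). Liver genes were higher in 12 of 20 and intestine genes in 16 of 19 with 1 lower, and in 16 and 16 with 1 lower adjusted over the list alone (adjusted p = 1.31e-06 and 5.39e-06, and 0.555 and 0.541 with an estimated correlation). Conjugation genes were higher in 14 of 23, 20 adjusted over the list alone, and Nrf2 genes in 12 of 21 with 1 lower, 16 and 2 adjusted over the list alone (1.29e-06 and 1.76e-05, and 0.541 for both with an estimated correlation).

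Cell cycle genes were higher with urban PM1 in 15 of 20 cases on the ratios, 16 adjusted over the list alone (median 0.48, adjusted p = 6.49e-07, and 0.487 with an estimated correlation), and their median turned to −0.06 in the Cy5 channel alone. Inflammation genes were lower in 9 of 14 and higher in 2, the same adjusted over the list alone (−0.62, adjusted p = 0.00015, and 0.487 with an estimated correlation), and in Cy5 alone the list did not pass, with a median of −0.10. Neural genes were lower in 7 of 25 (0.000392, and 0.515 with an estimated correlation), 10 with 1 higher adjusted over the list alone, and did not pass in Cy5 alone (median −0.21). Photoreceptor genes were lower in 11 of 41 and higher in 3 (8.13e-05, and 0.505 with an estimated correlation), and 17 and 3 adjusted over the list alone. Clock genes were lower in 6 of 23 and higher in 1 (0.00559, and 0.487 with an estimated correlation), the same adjusted over the list alone. Sterol synthesis genes were higher in 14 of 24, 15 with 1 lower adjusted over the list alone (1.25e-05, and 0.505 with an estimated correlation). Fatty acid oxidation (14 higher, 2 lower of 26), epidermis (8 and 1 of 25), heart (6 higher of 15) and leukocyte (6 of 12) lists passed camera at 0.000551, 0.000584, 0.000955 and 0.00184, and had 0.505, 0.745, 0.541 and 0.487 with an estimated correlation. Erythroid genes were higher in 3 of 14 (0.0212, and 0.727 with an estimated correlation), and their median turned from 0.36 to −0.03 in Cy5 alone. Of the lists that camera called between the sites, fry did not call erythroid (adjusted p = 0.141) and epidermis (0.158). It called cartilage and bone (0.00241), which camera did not.

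The control's own signal differed for several of these genes. The Cy3 level of ela2 was 12.6 log2 units on the urban arrays and 15.0 on the rural ones, that of fosab 10.8 and 9.05, and that of cyp1a 9.68 and 10.0. In the Cy5 channel alone the site difference was −2.16 for cyp1a, −1.10 for ahrra, −1.33 for cyp1b1, −1.95 for fosab, −1.81 for jdp2b and 2.96 for egln3, all past the threshold, whereas that of ela2 was 1.79 and did not pass. List medians in Cy5 alone were 1.29 for the pancreas (2.36 on the ratios), 0.72 for the lens (0.78) and 0.98 for the liver (1.51). They were 0.75 for the intestine (1.34), 0.42 for conjugation (0.98) and 0.22 for Nrf2 (0.75). Sterol synthesis had 0.20 (0.45) and fatty acid oxidation 0.21 (0.57), and all of these lists passed camera in Cy5 alone. On the 2 slides that carried both sites the ratios differed by −1.81 and −1.16 for cyp1a, −3.45 and −3.88 for fosab, and 5.44 and 4.81 for ela2. The first values set PM1 May replicate 2 against November and December replicate 1. The second values set PM1 February replicate 2 against November and December replicate 2. Each thus rests on a single urban pool and still holds the difference of the controls. November replicate 1 includes its technical repeat on slide 5.

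**Figure D3:**
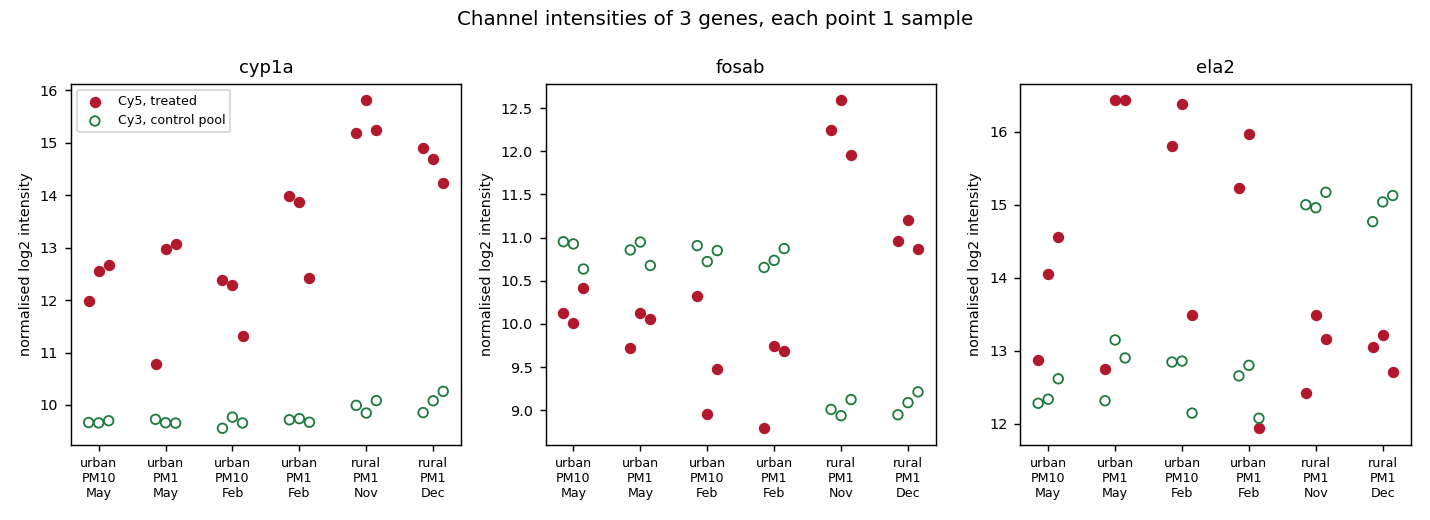
Normalised log2 intensity (vertical axis) of cyp1a, fosab and ela2 in the Cy5 channel of exposed embryos and the Cy3 channel of control, 1 point per sample and channel, by extract. The Cy3 level of ela2 averages 12.6 on urban and 15.0 on rural arrays.

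The sites differed in 5561 genes, 3217 higher and 2344 lower with urban PM1, and 729 of these by 2-fold or more. Of the 5561, 5023 (90.3%) had the same sign in Cy5 alone and 337 also passed there with that sign, where 567 genes passed in all. The count was 2561 with a slide block (1556 higher, 1005 lower), and 28 in Cy5 alone with a slide block. Median centring gave 3294 higher and 807 lower. Leaving out PM1 May replicate 1, 2 or 3 gave 11045, 2285 and 2076 genes, PM1 February replicate 1, 2 or 3 gave 2951, 2096 and 9008, November replicate 1 or 3 gave 3183 and 3651, and December replicate 3 gave 2473.

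Particle size at the urban site was compared over both months. No single gene passed, but photoreceptor genes stood higher with PM10 than with PM1 as a group. They included guca1c and the cone kinases grk7a and grk1b, which restore cones after light, the cone phosphodiesterase genes pde6c and pde6ha, and both cone arrestins. Of these, guca1c, grk7a, grk1b, pde6c and pde6ha also differed between the urban months and had the opposite sign between the rural months. A condition such as the hour of sampling, a candidate explanation for the month genes, was not tested for PM10 against PM1. Each size came as a single extract per month, so particle size cannot be told apart from such a condition and both stay open. cyp1a and the other AhR genes did not pass.

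Of 41 photoreceptor members measured, 38 were above 0 and 11 were higher adjusted over the list alone, with 0 over all genes by limma. The list's median was 0.29 (camera adjusted p = 2.83e-32, and adjusted p = 0.0295 with an estimated correlation), and fry gave an adjusted p of 0.00387. The median held between 0.22 and 0.39 in 32 alternatives, and was 0.39 in May and 0.19 in February. Several of the alternatives, such as leaving out a rural sample or using trend and robust variances, cannot move this median. Members past the threshold adjusted over the list alone, chosen after their values were seen, included pde6ha (1.05 ± 0.21), guca1c (0.76 ± 0.14), grk7a (0.54 ± 0.10), pde6c (0.52 ± 0.10), rbp3 (0.51 ± 0.11), arr3b (0.45 ± 0.09) and grk1b (0.44 ± 0.09). cyp1a was at −0.62 ± 0.39 and cyp1b1 at −0.30 ± 0.17. Camera also called clock, neural, skeletal muscle, pancreas, glucocorticoid, metallothionein and hypoxia, leukocyte and lens genes, with 0.28, 0.505, 0.505, 0.745, 0.487, 0.401, 0.541 and 0.877 as adjusted p with an estimated correlation. The pancreas and leukocyte medians were lower with PM10 (−0.25 and −0.11) and the other 6 higher, and the lens call ended with a slide block (median 0.15). In limma 0 of 24655 genes passed and 505 had an unadjusted p under 0.05, and under median centring 1 passed, pde6ha. With a block for the urban pairs, chosen after seeing the data, 0 passed in limma and 1202 had an unadjusted p under 0.05. With that block 23 photoreceptor members were higher adjusted over the list alone, and camera also called the conjugation, epidermis, intestine and Nrf2 lists at the preset correlation but not with the estimated one (0.739, 0.804, 0.739 and 0.765). fry with the block called the clock, neural and metallothionein and hypoxia lists too, which it did not call without it.

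The urban months were compared over both particle sizes. Of the 21 genes lower in February, 5 are in the photoreceptor list, such as guca1c, grk7a and pde6c of the cone light response, and 2 in the clock list, bhlhe40 and per1b, which light resets. The activin subunit inhbb and the GABA receptor subunit gabra6a were lower too. guca1aa, a second activator of the photoreceptor cyclase, and lrata, which stores retinol, were higher. AhR genes did not pass.

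guca1c differed by −1.34 ± 0.14 (adjusted p = 0.000363), bhlhe40 by −1.24 ± 0.15, grk7a by −1.23 ± 0.10 (adjusted p = 9.53e-05), inhbb by −0.95 ± 0.09, pde6c by −0.75 ± 0.10, gabra6a by −0.71 ± 0.07 and per1b by −0.59 ± 0.10, each with 12 of 12 samples beyond the other month's mean. guca1aa was higher by 0.97 ± 0.13 and lrata by 0.48 ± 0.08. The phosphatase ppm1na (−0.71 ± 0.11), the oxysterol-binding gene osbpl7 (−0.66 ± 0.08) and the cone kinase grk1b (−0.58 ± 0.09) were lower. Of 41 photoreceptor members 5 were lower and 1 higher, 8 and 1 adjusted over the list alone (median −0.10, camera adjusted p = 2.11e-06, and 0.487 with an estimated correlation). Of 23 clock members 2 were lower, 5 adjusted over the list alone, although the list's median was 0.00 and its mean −0.10 (adjusted p = 0.0307, and 0.505 with an estimated correlation). Cell cycle (−0.16), chaperone (−0.17) and pancreas (0.28) lists passed camera at 0.00024, 0.000664 and 0.00865, and had 0.541, 0.37 and 0.757 with an estimated correlation. With a slide block the pancreas list did not pass (median 0.11), nor did the clock list in Cy5 alone. cyp1a was at 0.36 ± 0.39.

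**Figure D4:**
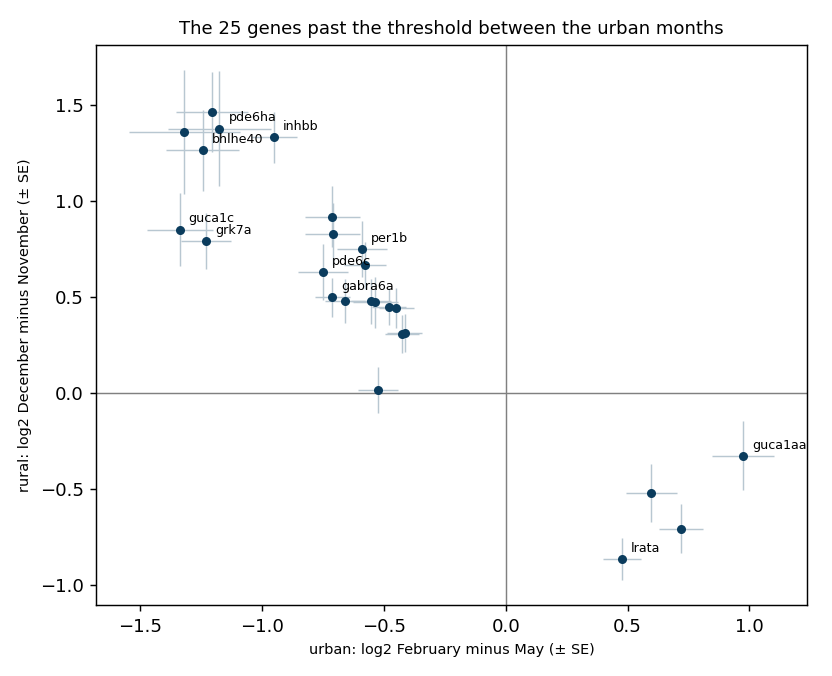
Log2 difference February minus May in urban samples (horizontal axis) against December minus November in rural samples (vertical axis) for the 25 genes that passed between the urban months, 1 point per gene with standard errors. All 25 have opposite signs on the axes.

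The months differed in 25 genes, 4 higher and 21 lower, 6 of them by 2-fold or more, and 1190 genes had an unadjusted p under 0.05. With a slide block 5 passed (guca1c, grk7a, inhbb, gabra6a and lrata), and with trend and robust variances, or in Cy5 alone, 16. With the urban pairs as a random effect, chosen after seeing the data, 5 passed (guca1c, grk7a, inhbb, gabra6a and si:ch211-81a5.8), so that bhlhe40, pde6c, per1b, guca1aa, lrata, ppm1na, osbpl7 and grk1b did not. Median centring gave 1 higher and 24 lower. The count was 16 without PM10 May replicate 1 or 3 or PM1 May replicate 1, 12 without PM1 May replicate 2 or PM10 February replicate 1, and 11 without PM10 February replicate 2 or PM1 February replicate 1 or 2.

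For the rural months, 7 genes differed. inhbb was higher in December by 1.33 ± 0.13 (limma adjusted p = 0.00115, 6 of 6 samples) and pik3r3a, a subunit of a growth signalling kinase, by 0.93 ± 0.12. lrata was lower (log2 difference −0.86 ± 0.11). Of the 7 genes 4 were higher and 3 lower, and 1685 had an unadjusted p under 0.05. Median centring gave 6 higher and 1 lower, where inhbb passed and lrata and pik3r3a did not. A slide block left inhbb and lrata, and with the mean of a gene's probes pik3r3a did not pass. The count was 16 without PM1 May replicate 1, 3 without November replicate 1, 2 without November replicate 2, 13 without November replicate 3 and 3 without December replicate 2, and 12 in Cy5 alone. Whether the effect of particle size differed between May and February was tested as an interaction at the urban site, where 0 of 24655 genes passed in limma and 362 had an unadjusted p under 0.05. With a block for the urban pairs, 0 passed in limma and 1050 had an unadjusted p under 0.05.

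**Figure D5:**
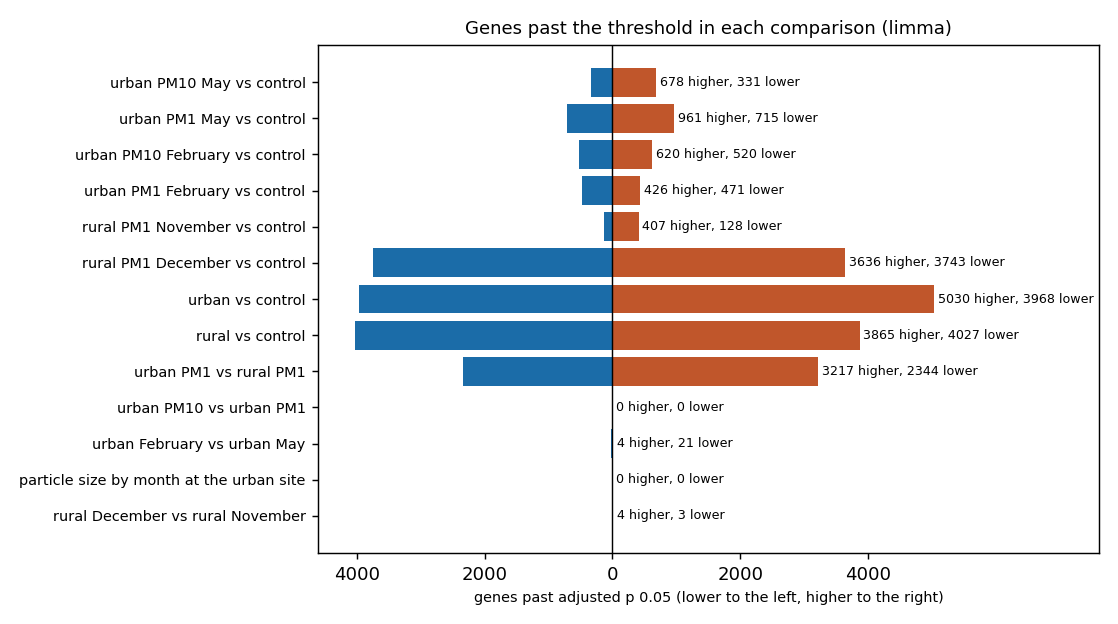
Number of genes past an adjusted p of 0.05 above 0 (up) and below 0 (down) in each of the 13 comparisons, as bars on the axis of gene counts. Bars run from 0 for PM10 against PM1 to 5030 above and 3968 below control for all urban samples.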

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

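All tests of the control pools in this part were chosen after the results were seen, whereas the count over other splits of the samples was set before the data were examined.

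A set of genes moved in opposite directions at the sites. A total of 705 genes were above control with the urban extracts and below it with the rural ones, and 278 were below it with the urban and above it with the rural extracts, with the site difference itself past the threshold for every gene. The first set holds the elastase ela2, the thyroid hormone carrier ttr and the lens crystallin cryba1l1. The second holds fosab and klf4, which respond early to stimulation, and tsc22d3, which glucocorticoids induce.

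The control channel, which no comparison was planned on, differed between the arrays of the sites. In Cy3, 11939 of 24655 genes differed, 5568 higher and 6371 lower on the urban arrays, 214 of them by 2-fold or more. The control channels correlated across genes at 0.987 or more within the urban and within the rural arrays, and at up to 0.990 between them. Genes of both sets were among them: ela2 was at 12.6 log2 units on the urban arrays and 15.0 on the rural ones, npas4a at 10.4 and 8.40, and klf4 at 8.82 and 7.58. On the self-to-self array 3 genes had a ratio of 2-fold or more, all above 0, where a ratio of 0 is due, and the SD of all its log2 ratios was 0.15.

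The site difference was set against different control pools as its whole cause, in which case the exposed embryos' own channel would show none. For the 10 genes with the largest falls, picked by their ratios, a median share of 0.522 of the difference remained in Cy5 alone and 8 of the 10 passed there, which argues against the control as the whole cause for that set. For the 15 cell cycle members past the threshold the share was −0.00553, with 7 of 15 keeping their sign, so unequal control pools are a candidate explanation for that list. For the 10 largest rises (share 0.477, 0 of 10 past the threshold in Cy5 by limma, 10 of 10 with the same sign), the 11 inflammation members (0.314, 0 of 11 past, 8 of 11 with the same sign) and the 12 AhR members (0.744, 4 of 12 past, 10 of 12 with the same sign; a division by size made after this stayed open gave 0.772 with 3 of 4 past for members 2-fold or more apart and 0.628 with 1 of 8 past for the others), control and exposure cannot be told apart for the sets as a whole, because too few genes pass in Cy5 alone, although the single AhR genes cyp1a (−2.16), cyp1b1 (−1.33) and ahrra (−1.10) passed there and nqo1 (0.11) did not, and the whole AhR list passed camera there (median −0.17) with a median Cy3 difference of 0.06 over the 12 members. The Cy5 channel alone has no control beside it. It cannot tell exposure from any other difference between the embryos used for the 2 sites. A difference between the air of the sites stays open and untested, since each site gave 1 extract per month and the months differ too.

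Of 100 splits of the 12 PM1 samples drawn from 462, 2 gave as many genes as the division by site, the real one among them. The real count was 5561 and the highest other 8001. The share of such splits was under 0.05 where no account is taken of the slide, and with a slide block the real count was 2561. The splits treat pools of the same extract as exchangeable with the others. The control pools also differed along the division by site, so this count cannot tell exposure from control. Deviations from the extract means, between samples of different extracts, correlated at a median of 0.288 on the same slide and 0.0164 on other slides. A split that calls more genes than the real one points to a structure of the samples beyond the site. It set PM1 May replicates 2 and 3, PM1 February replicates 1 and 2, November replicate 1 and December replicate 1 against the rest. This puts all 3 PM1 samples of slide 2 and scan day 1 on 1 side, with November replicate 1 counted by its first array. Its technical repeat was on slide 5 and scan day 2. Both exposed samples unique to slide 5 are on the other side, and those of slides 1, 3 and 4 are parted. The split also parts the urban pools by liver list median. PM1 May replicate 1 (−0.81) and PM1 February replicate 3 (−0.89) are among the rest, and the other PM1 urban pools were at 1.28 to 1.37. Rural medians were below 0 on both sides.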

How the results depend on the processing

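All alternatives were chosen before the data were examined, except the Cy5 channel alone with or without a slide block and the fits with urban pairs, which were chosen after seeing the data. With the deposited ratios all 461 named values and all 130 list results kept their direction and side of the threshold, and every count stayed within 1.5 times, as it also did with no background subtraction, no filter on dim probes, the mean of a gene's probes, a replicate block, a scan day block or without the technical repeat. The limits are 3 pools per extract, 1 self-to-self array for the dye, and control pools that differ by site. Signal over background limits the dim genes, since 47.8% to 87.4% of probes were well above background in Cy3. A dye term from 1 array widens every error, so calls end by its construction. A slide block leaves 8 residual degrees of freedom in place of 12, and the strict filter tests fewer genes. Where not so stated, the cause was not tested.

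Median centring in place of loess kept 388 of 461 named values, with 57 weaker, 3 stronger and 13 turned. It called 6932 genes for PM10 May, 5978 for PM1 May, 3017 for PM10 February, 571 for PM1 February, 284 for November, 4090 for December, 14402 for urban, 4788 for rural and 1 for PM10 against PM1. The median of all genes moved by 0.16 with PM10 May, 0.15 with PM1 May, and 0.11 with PM10 February and over the urban samples. In urban embryos it turned arr3a (0.0428), ckma (0.44), fabp7a (0.10), gap43 (0.0910), gfap (0.15), hspa8 (0.0767), krt1-19e (0.20), mtf1 (0.16), myh7 (0.0357), olig2 (0.0152) and ryr1b (0.0372) to above control and pparg to −0.0396, and between the sites mylpfa to 0.0293. Of these only ckma passed after the turn. Relative to the urban median of all genes (0.12), arr3a (−0.08), fabp7a (−0.02), gap43 (−0.03), hspa8 (−0.04), myh7 (−0.08), olig2 (−0.10) and ryr1b (−0.08) stayed below 0. On that scale ckma (0.32), gfap (0.03), krt1-19e (0.08) and mtf1 (0.04) were above 0. Median centring turned the urban chaperone (0.23), neural (0.20) and photoreceptor (0.26) lists, the skeletal muscle list between sites (0.41) and the neural list between months (−0.18).

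The strict filter called 608 genes for PM10 May. With a slide block the counts were 257 for PM10 May, 803 for PM1 May, 531 for PM10 February, 324 for PM1 February, 356 for November, 5631 for urban, 2561 for the sites, 5 for the urban months and 2 for the rural months, with 395 named values kept and 66 weaker. With the dye term they were 1 for PM10 May, 3 for PM1 May, 1 for PM10 February, 2 for PM1 February, 15 for November, 5 for December, 1 for urban and 14 for rural. Of 294 named values 29 were kept, 264 were weaker and rural tiparp turned to −0.11, and the urban skeletal muscle list turned to −0.16. Trend and robust variances gave 733 for PM10 February, 526 for PM1 February and 16 for the urban months. The mean of probes turned rural mylpfa (−0.0226) and per2 (0.0331).

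In Cy5 alone 567 genes differed between the sites, 16 between the urban months and 12 between the rural months, and with a slide block 28, 6 and 0, the last by limma with 10.2% of genes at an unadjusted p under 0.05. Cy5 alone turned the site difference of ccnb2 (−0.12), foxq1b (−0.00986), urod (−0.17), fkbp5 (0.23), gadd45ba (0.32), klf9 (0.20), mt2 (0.34), pdk2b (0.21) and wfikkn1 (0.0123), and of the cell cycle (−0.0623), erythroid (−0.0270) and metallothionein and hypoxia (0.20) lists. With a slide block added, fkbp5 (0.10), gadd45ba (0.17) and mt2 (0.36) were turned.

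Leaving out 1 sample at a time, which leaves 2 for its extract, counts ran from 241 to 1483 for PM10 May, 232 to 4991 for PM1 May, 126 to 1681 for PM10 February, 145 to 1404 for PM1 February, 96 to 982 for November, 1393 to 9645 for December, 7351 to 11090 for urban, 4435 to 9763 for rural, 2076 to 11045 for the sites, 11 to 25 for the urban months and 2 to 16 for the rural months. Both PM10 against PM1 and size by month stayed at 0 throughout in limma, against 505 and 362 genes at an unadjusted p under 0.05 with all samples. For PM10 against PM1 the lens list ran from 0.0182 to 0.237 and the liver list from −0.280 to 0.326, and without PM1 May replicate 1 or PM1 February replicate 3 the camera direction of the lens list turned (medians 0.0333 and 0.0182) and so did the liver list (−0.270 and −0.280). Between the urban months the liver list ran from −0.357, without PM1 May replicate 1, to 0.399.

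With a replicate block of urban pairs PM10 against PM1 and size by month stayed at 0 in limma (1202 and 1050 genes at an unadjusted p under 0.05), the conjugation (−0.0532), epidermis (−0.0539), intestine (−0.100) and Nrf2 (−0.0433) lists passed camera, and no other call of camera, or of genes over all genes, changed. Counts adjusted over the list alone did change, such as from 11 to 23 higher for photoreceptors and from 0 to 3 for metallothionein and hypoxia. With urban pairs as a random effect 6248 genes passed for urban and 5 for the urban months, with 16 of 143 named values weaker, 8 in each, among them urban ahr2 (0.21), mpx (0.36) and lcp1 (0.30).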

Other observations

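The tests of the organ lists over the urban samples and of the urban month genes were chosen after the results were seen, and the counts over other splits of the samples were set before.

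Beyond the groups described for each comparison, several single genes of the skin, eye and hormone systems changed. In urban embryos the keratin krt94 rose by 0.81 ± 0.06 and the skin chemokine ccl27a by 0.85 ± 0.08, while the non-visual opsin opn6a fell by 0.87 ± 0.05, the lymphatic and lens regulator prox1a by 0.78 ± 0.16, the thyroid hormone receptor thrb by 0.51 ± 0.09 and the glucocorticoid-induced tsc22d3 by 0.50 ± 0.05. The fall of the opsin and of the cone and rod regulator crx (−0.56 ± 0.06) held in 12 of 12 samples.

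In rural embryos the stress factor atf3 rose by 0.94 ± 0.11, the growth factor binding protein igfbp1a by 0.96 ± 0.11 and the vessel growth factor vegfaa by 0.65 ± 0.17, each in 6 of 6 samples. The green cone opsin opn1mw2 rose by 0.83 ± 0.09, whereas rlbp1b, which carries retinal in glia and pigment cells of the eye, fell by 1.29 ± 0.19. The slow myosin smyhc2 fell by 1.34 ± 0.25 and the skin annexin anxa1b by 1.51 ± 0.25.

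Pancreas, liver, intestine and lens genes varied together between pools exposed to the same urban extract. As deviations from the extract means over 12 samples, the pancreas list median correlated with that of the lens list (r = 0.954, permutation p = 6e-05, adjusted 6e-05; rho = 0.874, permutation p = 0.00042, adjusted 0.00126), and r was 0.902 without the 2 samples farthest from the median. The values were r = 0.972 and rho = 0.832 for the liver (permutation p = 2e-05 and 0.00137, adjusted 3e-05 and 0.00144, r = 0.940 without the 2) and r = 0.957 and rho = 0.825 for the intestine (permutation p = 2e-05 and 0.00144, adjusted 3e-05 and 0.00144, r = 0.901 without the 2), in 3 relations with 100000 resamples each, which leave out the pairing of PM10 with PM1 and so give p-values that are too low. The r of 0.954 with lens genes argues against variation of the exocrine pancreas alone, and a range of the liver median of 2.18 within slide 1, which is 0.937 of the range of 2.32 over all urban samples (2.17 within slide 4), argues against the slide as the whole cause. A difference in the developmental stage of the pools may underlie it and stays open, since no stage was recorded per pool.

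The 25 genes that differed between the urban months had the opposite sign between the rural months, where 3 of them (inhbb, lrata and a probe without a symbol) passed and the lowest absolute difference was 0.02. They had a median absolute rural difference of 0.67, where 10000 random sets of 25 genes of like brightness had a median of 0.18 and a 95% point of 0.25, which puts the genes at percentile 100. The random sets were matched on brightness alone. Genes that move together would reach a high percentile, and share a sign, more easily than such sets, so the percentile is not a p-value. All 25 kept their sign and at least 0.5 of the difference with slide as a block, and 25 had the same sign within both slides that held all urban extracts. This argues against the slide as the whole cause for these 25 genes. They were picked for a difference in these same samples, and 4 urban samples lay on each of those slides. The outcome was therefore favoured in advance and does not exclude a part played by the slide. With the block the median size was 0.69 with a standard error of 0.097, against 0.71 and 0.095 without it, and 5 genes passed as the residual degrees of freedom fell from 12 to 8. guca1c, grk7a, bhlhe40 and per1b among them follow light or the clock, although the last 2 did not pass with the urban pairs as a random effect, so a condition that also differed between the rural months, such as the hour of sampling, is a candidate explanation, and the month of the air itself stays open.

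Splits of the samples into groups of the same size were counted for the other comparisons. For the urban months 7 of 100 splits gave as many genes as the real 25, with 8436 as the highest other, so chance cannot be excluded, and the 10 splits that keep all 6 urban pairs together, as the real one does, are too few for a share under 0.05 (highest other 7355). For PM10 against PM1 and for size by month the real count was 0 in limma (505 and 362 genes at an unadjusted p under 0.05), so that all 100 splits had to give as many and the test decides nothing, with highest others of 9611 and 8149. Splits that call several times the real count point to a structure of the urban samples other than size and month, and among the 32 splits by size that part all 6 pairs the highest other was 0. For the rural months there are 10 splits, too few for a share under 0.05, and the real count was 7 with 0 as the highest other.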
